A study of Mus musculus with 3 samples.

How the data were processed

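DNase-seq was carried out on liver of mouse embryos at 13.5 days, per the labels, in 3 libraries that the labels number as biological replicates 1, 2 and 3 of 1 experiment. The libraries formed 1 group, so values are given per library or as the mean and SD over the 3, and no test between groups was possible. All positions are in the mouse build mm10, per the labels.

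For each library the deposited files held 2 lists of peaks, a list of positions with a false discovery rate, and a list of footprints. The peaks were called by the authors on the filtered alignments of that library alone, per the text listing deposited with each library, and the peak caller and its version are not given in the sources used here. The signal of a peak is the value that the authors deposited in the signal column of the peak list, scaled per library by the authors: every value below 2 was a whole multiple of 1 step per library, within 0.02 steps, as a count divided by a library total would be. That reading is not stated in the labels, so counts and depths derived from it are given only as conditional, and no counting interval was computed from them. The deposited false discovery rate file gives an adjusted p-value (q-value) per interval of positions, and the values show that it lists only intervals of at most 0.05. The deposited footprint files hold the constant 0.01 in every row, whose meaning the labels do not state, so footprints carried no score. The looser peak list of each library overlapped positions with a false discovery rate of at most 0.05 at every peak and was taken as the main list, because its mean width was the smaller in all 3 libraries. The stricter list, whose peaks all overlapped positions of at most 0.001, was an alternative.

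Genes and transcription start sites (TSSs) came from the GENCODE M21 basic annotation of the same build, with 21827 protein-coding genes. A promoter was the 1000 bp on either side of any TSS of a protein-coding transcript of the gene, and had a peak where a peak overlapped it by at least 1 bp. Windows of neighbouring genes can overlap, and the neighbour is named where its window overlaps that of a named gene. The TSS of the neighbour need not lie in the window of the named gene. Promoter signal was the highest signal of a peak in the window, and a gene's percentile in a library is the percentage of protein-coding genes with a lower promoter signal, with genes without a peak at 0. A promoter without a listed peak is reported as that and not as closed chromatin. Peaks of the 3 libraries were merged where they overlapped, and a region was distal where it lay more than 1000 bp from a TSS of any gene type.

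The 15 gene lists (globin, erythroid, haem and iron, blood stem and progenitor cells, megakaryocyte, myeloid, lymphoid, hepatoblast, mature hepatocyte, endothelial, mesenchymal and stellate, neural, muscle, germline and housekeeping), the 21 motifs, the comparisons, the rule for named genes and most alternatives were chosen before the data were examined. Use of all TSSs of a gene was settled after the annotation was seen and before any list result, and the reading of which peak list is the narrower after the widths were seen. Of 315 list members 311 were used: H19 is non-coding, and Ahsp, Hbb-b1 and Hbb-b2 are not in the annotation used. No gene is on more than 1 list. Named genes were the 3 members of each list with the highest mean percentile and the lowest member, all globin genes, the regulators Gata1, Klf1, Tal1, Gata2, Runx1, Spi1, Hnf4a and Foxa2, the 10 promoter and 10 distal regions with the best worst rank of signal over the 3 libraries, and all motifs. Any other gene named is said to be chosen after its values were seen.

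The share of a list's genes with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test in each library, with Benjamini-Hochberg adjustment over the 15 lists. It was also compared with 10000 random lists of equal size matched on the number of CpG sites in the promoter, in 20 bins, by a two-sided permutation p. The median percentile of promoter signal was tested against the same kind of random lists, and the number of distal regions found in all 3 libraries within 50000 bp of the gene's TSSs against unmatched random lists. For promoter share and rank, a list was called only where the adjusted p was under 0.05 in the same direction in every library. The distal test was run on the pooled regions and not per library, so its calls rest on an adjusted p under 0.05 in that test alone. Genes are not replicates. Motifs were searched on both strands in footprints extended by 5 bp on each side. Control intervals were the same intervals moved by 100 bp to either side that overlapped no footprint and lay in a peak or in positions of the false discovery rate file. The odds ratio had 0.5 added to each count, and Fisher's exact test was adjusted over the 21 motifs. Each motif was also searched as its reversed string, as a control for base composition. Promoter windows copied elsewhere were found by aligning each window to the genome, and a promoter counted as copied where at least 50% of it matched elsewhere at an identity of at least 98%.

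The alternatives were equal numbers of the strongest peaks, the stricter peak list, reciprocal overlap of at least 50%, promoter windows of 500 and 2500 bp, unmatched random lists, the smallest false discovery rate in place of the signal, regions in at least 2 libraries, distances of 20000 and 100000 bp, footprints without extension, control intervals 50 and 200 bp away, and each replicate left out in turn. Added after the data were seen were the most upstream TSS alone, random lists matched on gene density, lists without copied promoters, and the strongest regions on the stricter list and without each replicate. The globin, erythroid, haem and iron, and hepatoblast lists were taken as main results for the alternatives after their values were seen. The yeast artificial chromosome was not analysed, since its sequence was not used here, and neither were alignments or read totals. The labels do not describe its insert, so whether reads from it were placed on matching mouse sequence, the globin loci included, was not tested.

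The list tests were tested on 100 simulated data sets with the 21827 genes. Of unchanged lists, 0% were called against matched lists and 16.5% against other genes, to which CpG content alone gives differences. Peaks were drawn gene by gene from the CpG bin alone, the bins that the matched lists use, so few calls against them were possible. The simulated libraries shared a set of open promoters and had equal detection. Differences in depth and clustering of genes were not simulated, so the 0% does not cover false calls from these. A list of 34 genes whose odds of a peak were raised 8 times was called in 58.0% of the data sets against matched lists and in 28.0% against other genes, and raised 20 times in 84.0% and 66.0%. The size at which recovery was required was raised from 8 to 20 times after the simulated results were seen. The step of the signal was recovered at 100% of its simulated size, and a motif simulated at an odds ratio of 5.21 was recovered at 5.85. Interval functions matched a plain loop for 400 genes, with 0 differences. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, and bedtools 2.31.1, samtools 1.23.1 and minimap2 2.31.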

Results

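Open chromatin was mapped by DNase-seq, in which the enzyme DNase I cuts accessible DNA and the cut ends are sequenced, in the liver of mouse embryos at 13.5 days. The labels describe wild-type mice of the strain C57BL/6N,129 that carry a single copy of a yeast artificial chromosome named A20, a large cloned piece of DNA whose sequence was not analysed here. The samples formed 1 group of 3 biological replicates with no treatment and no control tissue, so gene groups, regions and libraries of this tissue were compared with each other. The labels name 1 donor for all 3 libraries and a separate biosample for each, and how far the spread between them was technical is not known. No read totals were used here. Every peak signal below 2 was a whole multiple of 1 step per library to within 0.02 steps, and the steps were 0.0112, 0.00347 and 0.00692 in replicates 1, 2 and 3. If a step stands for 1 count, the depths stood as 1 to 3.22 to 1.62, and the median peak held 104, 111 and 101 counts.

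The regions open in all 3 libraries lay mainly at promoters. Promoters, taken here as the 1000 bp on either side of a transcription start site (TSS) of any gene type, held 57.4% of the 25817 regions found in all 3 libraries. A region or peak counted as promoter with an overlap of at least 1 bp and was otherwise placed by its midpoint. This raises the promoter share and its ratio to the genome. Promoters held 56.3%, 27.1% and 38.7% of the peaks of replicates 1, 2 and 3. The mean was 40.7% ± 14.7 (SD, n = 3), 9.31 ± 3.36 (SD, n = 3) times their share of the genome. Replicate 1, which had the fewest peaks, limits which regions are shared, so the share among shared regions depends on its peaks. With equal numbers of the strongest peaks the shares were 56.3%, 52.3% and 48.9%. Introns held 29.7% ± 8.22, sequence between genes 24.8% ± 5.59 and exons 4.85% ± 1.88 (SD, n = 3). Among 21827 protein-coding genes, 53.96%, 67.3% and 56.4% had a promoter peak in replicates 1, 2 and 3, a mean of 59.2% ± 7.12 (SD, n = 3).

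The libraries differed in how many regions they held, and the strong regions recurred. Replicates 1, 2 and 3 held 34369, 122281 and 60862 peaks, a mean of 72504 ± 45098 (SD, n = 3), which covered 7.30, 27.9 and 11.6 Mb. Merged, they gave 130485 regions, of which 25424 lay in 2 libraries and 79244 in 1. Of the latter, 66177 were in replicate 2, where their median signal was 0.219 against 2.61 for regions found in all 3 libraries. In replicate 1, 90.3% of the peaks overlapped a peak of replicate 2 and 80.2% a peak of replicate 3, whereas 25.1% of the peaks of replicate 2 overlapped replicate 1. The mean over the 6 ordered pairs was 60.1% ± 26.7 (SD, n = 6), and the Jaccard index in bp was 0.284 ± 0.0709 (SD, n = 3 pairs). Across the 25817 shared regions, which are not independent replicates, the Spearman correlation of signal was 0.891 between replicates 1 and 2, 0.791 between 1 and 3 and 0.944 between 2 and 3. On equal numbers of the strongest peaks the Jaccard index was 0.455. Among the regions found in both replicates 2 and 3, those at promoters had a peak in replicate 1 more often than those away from promoters in each quintile of signal. In the weakest quintile the shares were 28.8% and 15.3%. In the middle quintile they were 66.5% and 44.9%, and in the strongest 99.2% and 91.4%.

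**Figure D1:**
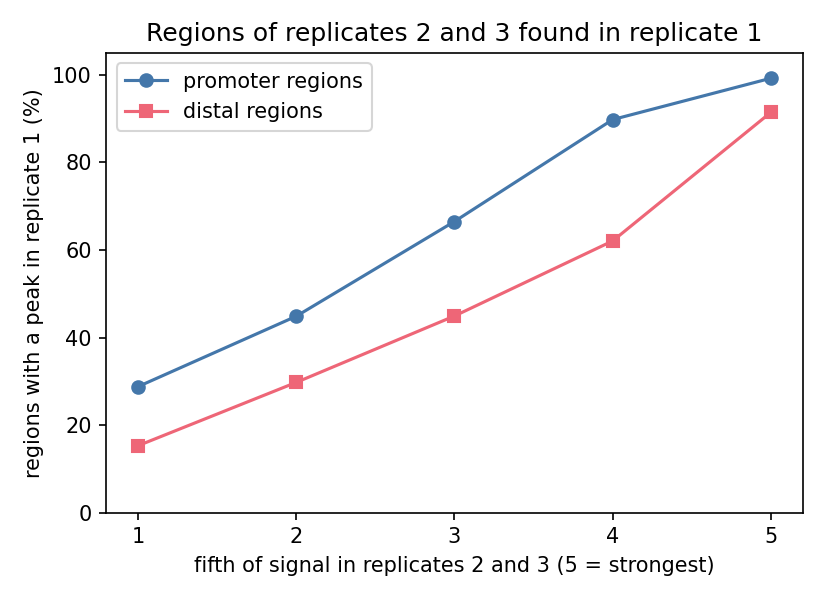
Percentage of the regions found in both replicates 2 and 3 that also had a peak in replicate 1, by quintile of their signal in replicates 2 and 3 (5 is the strongest), for promoter regions (circles) and distal regions (squares). Promoter regions lay above distal regions in all 5 quintiles, at 28.8% against 15.3% in the weakest and 99.2% against 91.4% in the strongest.

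Promoters of red cell genes were open in nearly every case. Of 34 erythroid genes, which encode transcription factors, membrane skeleton and surface proteins of red cell precursors, 30 had a promoter peak in all 3 libraries and the other 4 in 2. The mean share was 96.1% ± 6.79 (SD, n = 3), against 59.2% of the other protein-coding genes and 55.6% of random genes matched on promoter CpG content. The strongest was Epb41, which encodes a protein of the membrane skeleton. Zfpm1, a cofactor of GATA1, and Bpgm, an enzyme that sets how readily haemoglobin releases oxygen, came next. Epb41 (chromosome 4, 131923413 to 132075321 in mm10) had promoter signals of 10.2, 40.8 and 34.3 in replicates 1, 2 and 3. They were higher than those of 99.9% ± 0.0896 (SD, n = 3) of protein-coding genes. The window of Epb41 overlapped that of Gm10300. The corresponding percentiles were 98.8 ± 1.53 for Zfpm1 and 94.9 ± 0.989 for Bpgm (SD, n = 3). The lowest member was Pklr, pyruvate kinase of liver and red cells, with no peak in replicate 1 and signals of 2.49 and 2.05 in replicates 2 and 3. The red cell regulators Gata1, Klf1 and Tal1 had a promoter peak in all 3 libraries, at percentiles of 62.2 ± 8.09, 68.0 ± 11.1 and 78.1 ± 3.51 (SD, n = 3).

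Genes for haem and iron, which red cell precursors use in quantity, were open nearly as often. Of 19 such genes, 17 had a promoter peak in all 3 libraries, and the mean share was 93.0% ± 3.04 (SD, n = 3). Blvrb, a biliverdin reductase, stood at percentile 98.3 ± 2.49, Tfrc, the transferrin receptor, at 96.9 ± 1.60 and Glrx5, which serves iron-sulphur cluster assembly, at 96.4 ± 4.67 (SD, n = 3). The window of Blvrb overlapped that of Sptbn4. Alas2, the rate-limiting enzyme of haem synthesis in red cells, had a peak in replicates 2 and 3, with signals of 0.705 and 0.637. It was singled out after its values were seen. Slc25a37, which imports iron into mitochondria, had no listed peak in any library, and 100% of its promoter window is copied elsewhere in the genome. All 20 housekeeping genes had a promoter peak in all 3 libraries. Among them Rplp0, a ribosomal protein, stood at 98.8 ± 0.597, Actb, cytoplasmic actin, at 97.9 ± 1.37 (SD, n = 3). Sdha, a subunit of succinate dehydrogenase whose window overlapped that of Ccdc127, stood at 95.5 ± 2.86. Gusb, a lysosomal enzyme, was the lowest at 58.8 ± 2.70 (SD, n = 3).

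The erythroid, haem and iron, and housekeeping lists had promoter peaks more often than other genes in 3 of 3 libraries, with highest adjusted p-values of 0.000137, 0.0246 and 0.00247 (two-sided Fisher's exact test, 15 lists). Against random lists matched on CpG content, the erythroid list was higher in 3 of 3 libraries (adjusted permutation p = 0.0015 in each; the lists give no p below 0.0002 before adjustment). The haem and iron list (81.1% in matched lists) and the housekeeping list (86.5%) did not pass this test, with a highest adjusted permutation p of 0.933 for both. The housekeeping list could not have passed: its share in replicate 2 was 100%, the most possible, against 94.8% in matched lists. The haem and iron list had little room there, at 94.7% against 89.2%. In replicates 1 and 3 the haem and iron list had more room and did not pass either. There it stood at 89.5% against 76.9% (adjusted permutation p = 0.301) and at 94.7% against 77.1% (0.0795). The test thus cannot decide whether the housekeeping list exceeds what CpG content gives. For the haem and iron list it found no excess that passed in any library. The median percentile of promoter signal was 71.7 ± 10.1 (SD, n = 3) in the erythroid list against 38.4 in matched lists. It was 88.3 ± 2.38 against 66.6 in the haem and iron list and 88.4 ± 1.13 against 69.3 in the housekeeping list (SD, n = 3). All 3 were higher in 3 of 3 libraries, with highest adjusted permutation p-values of 0.0315, 0.0210 and 0.0195. These rank calls ended when the smallest false discovery rate in the window replaced the signal (medians of 63.8, 81.3 and 85.0), and the erythroid rank call also ended with the most upstream TSS of each gene alone (69.5). The haem and iron call against other genes ended with windows of 2500 bp (94.7%) and with the most upstream TSS alone (80.7%).

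**Figure D2:**
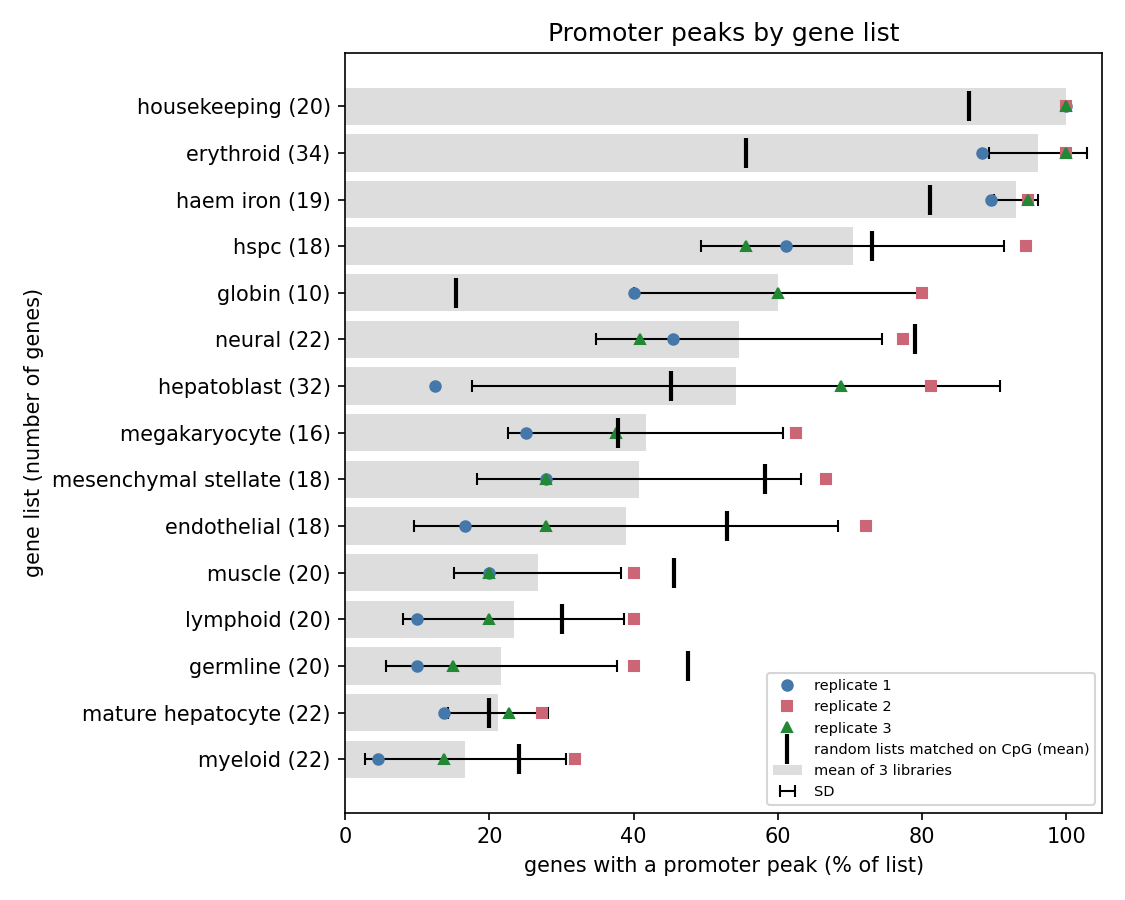
Percentage of the genes of each list with a promoter peak, with the number of genes in brackets; bars are means of 3 libraries, whiskers their SD, coloured points the libraries, and black ticks the mean of random lists matched on CpG content. The erythroid list (96.1%) lay far to the right of its matched lists (55.6%), and the hepatoblast list spread from 12.5% in replicate 1 to 81.3% in replicate 2, which was 18.75% with equal numbers of the strongest peaks.

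At the globin genes, promoters of adult beta-globin and of theta-globin were open in every library, and those of embryonic globins were not. Hbb-bs and Hbb-bt, which encode adult beta-globin, and Hbq1a and Hbq1b, the theta-globin genes, had a promoter peak in all 3 libraries, at percentiles of 64.9 ± 10.8, 59.4 ± 10.9, 61.7 ± 0.752 and 68.9 ± 4.59 (SD, n = 3). Hba-a1 and Hba-a2, which encode adult alpha-globin, had one in replicates 2 and 3. The embryonic genes Hbb-y and Hba-x had one in replicate 2, with signals of 0.632 and 0.410, and Hbb-bh1 and Hbb-bh2 in none. The share over the 10 globin genes was 60.0% ± 20 (SD, n = 3). This was higher than the 15.3% of lists matched on CpG content in 3 of 3 libraries (highest adjusted permutation p = 0.0165) and not different from the 59.2% of other genes (highest adjusted p = 1, Fisher's exact test). The median percentile, 38.0 ± 32.9 (SD, n = 3), did not pass the rank test (highest adjusted permutation p = 1); it was 56.99 and passed without replicate 1, and 48.1 and passed with windows of 2500 bp. Of the promoter windows of Hba-a1 and Hba-a2, 90.6% and 97.7% are copied elsewhere in the genome, so a peak in either cannot be placed with certainty. The globin genes lie in clusters and are not independent, and in replicate 1 the only peaks were those of Hbb-bs, Hbb-bt, Hbq1a and Hbq1b. The permutation p, from lists drawn over the whole genome, can thus overstate the evidence.

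The alpha- and beta-globin clusters were both dense in open regions. The alpha-globin cluster (chromosome 11, 32276400 to 32300873) with 100000 bp on either side held 16 regions found in all 3 libraries, or 7.13 per 100 kb against 0.947 over the genome. The beta-globin cluster (chromosome 7, 103812524 to 103853216) with the same flanks held 7, or 2.91 per 100 kb; no test was run on these densities. Over the 3 libraries the alpha locus held 43.3 ± 28.1 and the beta locus 18.7 ± 10.7 regions (SD, n = 3). Among the peaks of a library, the promoter of Snrnp25, which encodes a component of the minor spliceosome, stood at percentile 97.3 ± 2.87 and that of Nprl3, which encodes a regulator of the mTORC1 pathway, at 94.2 ± 2.503 (SD, n = 3). Introns of Nprl3 are known to hold distant enhancers of the alpha-globin genes. There, the region from 32245701 to 32245920 stood at percentiles of 62.9, 96.3 and 98.4 in replicates 1, 2 and 3. The region from 32250941 to 32251200 stood at 45.5, 94.4 and 98.4. That from 32256161 to 32256420 had a peak in replicates 2 and 3 alone, at 92.6 and 94.7. Upstream of Hbb-y, on the side that holds the known control region of the beta-globin genes, a region 7785 bp from its TSS (103861001 to 103861200) stood at 81.1, 97.0 and 97.3. Another 12565 bp away (103865781 to 103866000) stood at 7.77, 87.9 and 93.3. Without replicate 1 the regions found in every library used numbered 38 and 17, and on the stricter peak list 10 and 3.

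**Figure D3:**
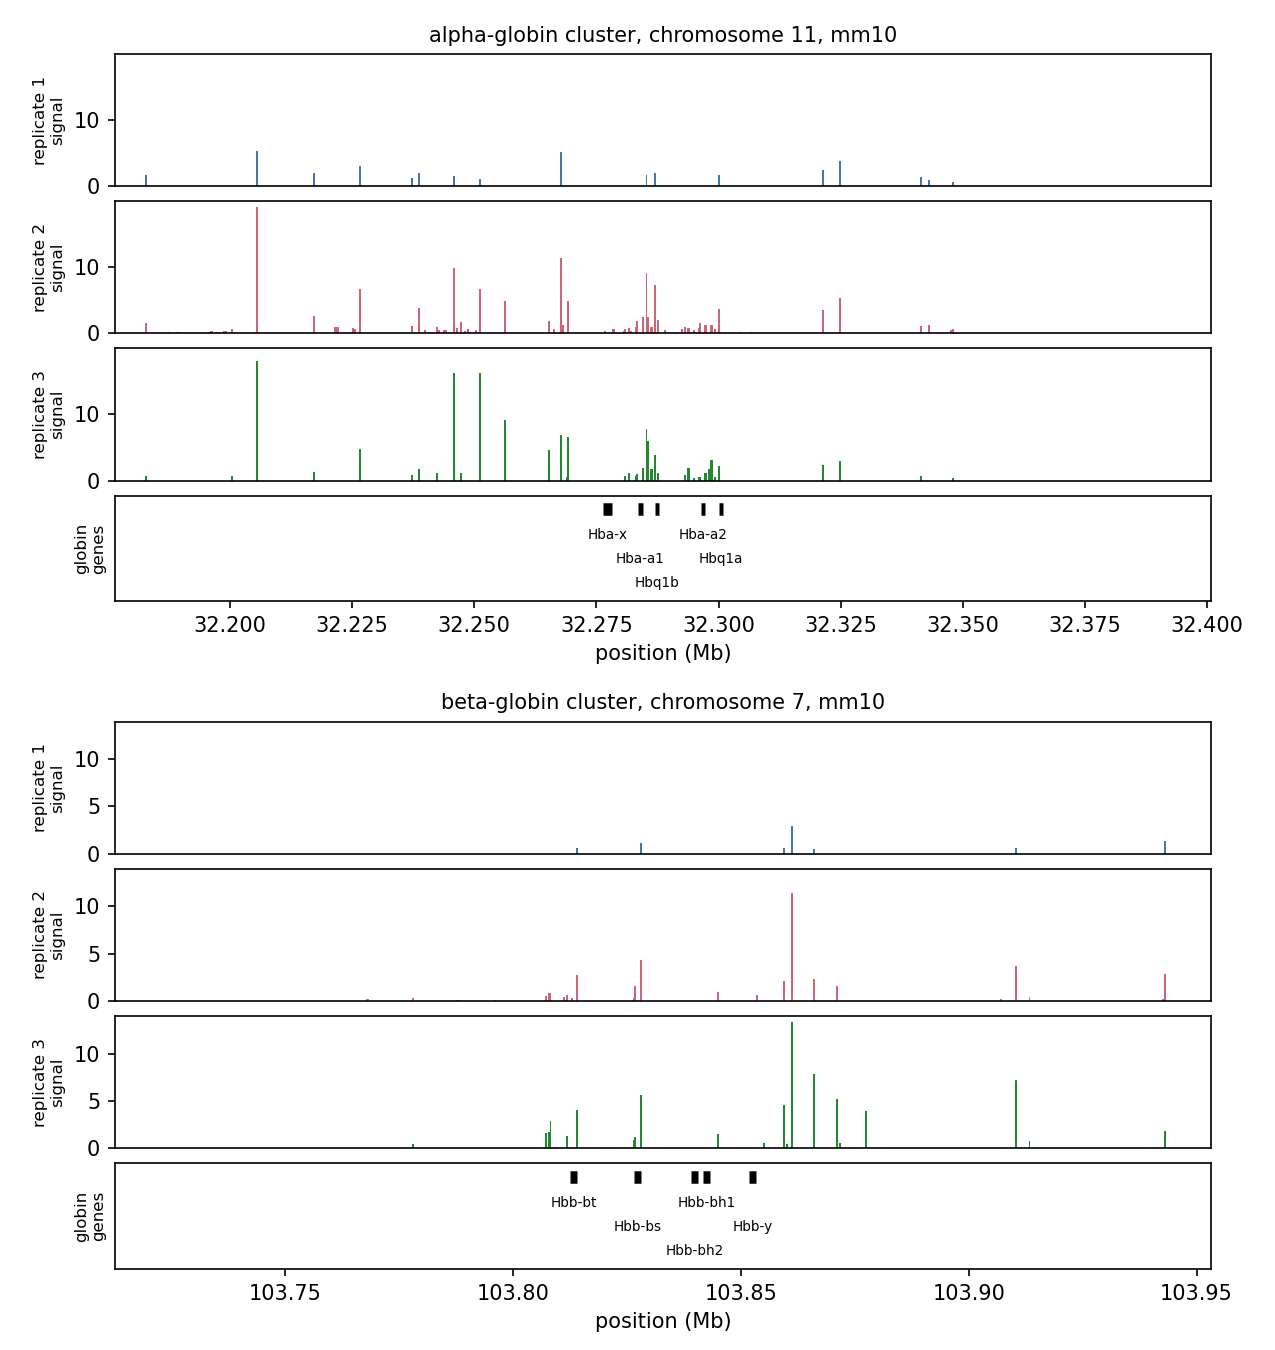
Peak signal (vertical axis, in the authors' units, same scale within a locus) along the alpha-globin cluster and the beta-globin cluster with 100000 bp on either side in mm10, in replicates 1, 2 and 3, with the globin genes as black boxes; bars are drawn at least 400 bp wide to be visible. Outside promoters, the tallest bars in replicate 3 are those in introns of Nprl3 (32245701 and 32250941) and upstream of Hbb-y (103861001), and all of these are lower in replicate 1 than in replicates 2 and 3.

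Promoters of hepatoblast genes, which the immature liver cells of the embryo express, had the widest spread between libraries of the 15 lists. They had a peak for 12.5% of the 32 genes in replicate 1, 81.3% in replicate 2 and 68.8% in replicate 3, a mean of 54.2% ± 36.6 (SD, n = 3). With equal numbers of the strongest peaks these shares were 12.5%, 18.75% and 43.75%, a mean of 25.0%, and on the stricter peak list 6.25%, 43.75% and 53.1%, a mean of 34.4%. In all 3 libraries a peak was found at Foxa3, a liver transcription factor, at percentile 84.4 ± 2.13, and Hhex, a homeobox factor of early liver, at 58.9 ± 3.16 (SD, n = 3). So it was at Trf, the iron carrier transferrin, at 52.1 ± 2.53, and Prox1, a homeobox factor of hepatoblasts, at 49.4 ± 0.521 (SD, n = 3). The windows of Foxa3 and Trf overlapped those of Sympk and Gm20425, and Prox1 was named after its values were seen. Another 17 members had a peak in 2 libraries, 6 in 1 and 5 in none. Afp, the alpha-fetoprotein gene, had no peak in replicate 1 and signals of 0.639 and 0.623 in replicates 2 and 3, and was chosen after its values were seen. The liver regulators Hnf4a and Foxa2 had no peak in replicate 1, and Foxa2 had one in replicate 2 alone, with a signal of 0.556. The 5 members without a listed peak were Alb, Apoc3, Cps1, Serpina1a and Serpinc1. The last, which encodes antithrombin, was named by rule and the others after their values were seen. In the promoter window of Alb, replicate 3 had 2 intervals of positions with a false discovery rate of at most 0.05, the nearest 1 bp from the TSS. For Serpina1a, Cps1, Apoc3 and Serpinc1 the nearest such position in any library lay 1937, 2583, 4915 and 8393 bp from the TSS, and whether the authors left such stretches out is not known. Over all 3 libraries the list was not called against other genes (highest adjusted p = 0.244, Fisher's exact test), against matched lists (45.2%) or in rank (median percentile 31.2 ± 27.2, SD, n = 3; 46.8 without replicate 1). Against matched lists it was lower in replicate 1 and higher in replicates 2 and 3 (adjusted permutation p of at most 0.002 in each), and without replicate 1 it was called higher, at a mean percentile of 99.995 among them. With equal numbers of the strongest peaks the direction turned in replicate 2, where it was lower (18.75% against 37.3%, adjusted permutation p = 0.0141), and it was not called in replicate 3 (43.75% against 34.8%, 0.310). On the stricter list it was called in neither replicate 2 (43.75% against 45.6%, adjusted permutation p = 1) nor replicate 3 (53.1% against 37.6%, 0.0580).

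Genes of other liver cells had a lower mean share than hepatoblast genes, a difference that was not tested and that turned in some libraries and settings. In replicate 1 the mature hepatocyte (13.6%), endothelial (16.7%) and mesenchymal (27.8%) lists lay above the hepatoblast list (12.5%). With equal numbers of the strongest peaks the mesenchymal mean (24.1%) was close to that of the hepatoblast list (25.0%), and in replicate 2 it was the higher (22.2% against 18.75%). Genes of mature hepatocytes had a peak in 21.2% ± 6.94 of 22 cases (SD, n = 3). Glul, glutamine synthetase, stood at percentile 80.2 ± 2.88, Gls2, a glutaminase of liver, at 68.0 ± 2.07 and Pck1, an enzyme of glucose synthesis, at 31.3 ± 27.7 (SD, n = 3). Uox, urate oxidase, had none. The windows of Glul and Uox overlapped those of Teddm2 and Dnase2b. Endothelial genes had a peak in 38.9% ± 29.4 of 18 cases (SD, n = 3). Plvap, a component of vessel fenestrae, stood at 59.3 ± 3.28, Kdr, the main receptor for vascular endothelial growth factor, at 48.6 ± 2.12 and Egfl7, a secreted endothelial protein, at 37.3 ± 32.3 (SD, n = 3). The window of Egfl7 overlapped that of Gm20532. Stab2, a scavenger receptor of liver sinusoids, had none. Genes of mesenchymal and stellate cells had a peak in 40.7% ± 22.5 of 18 cases (SD, n = 3). Col1a1, a chain of collagen type I, stood at 57.3 ± 0.685, Pdgfra, a receptor for platelet-derived growth factor, at 56.6 ± 5.18 and Reln, which encodes reelin, at 54.1 ± 0.817 (SD, n = 3). Postn, a matrix protein, had none.

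Genes of other blood lineages were open less often than erythroid genes by mean share, a difference that was not tested. Genes of blood stem and progenitor cells had a peak in 70.4% ± 21.0 of 18 cases (SD, n = 3). Lyl1, Runx1 and Lmo2, transcription regulators of blood formation, stood at percentiles of 94.6 ± 3.20, 75.05 ± 0.545 and 74.7 ± 12.4 (SD, n = 3). Ly6a, the stem cell marker Sca-1, had none, and Gata2, a regulator of blood stem cells, had one in replicate 2 alone, with a signal of 1.19. Megakaryocyte genes had a peak in 41.7% ± 19.1 of 16 cases (SD, n = 3). Thbs1, which encodes thrombospondin, Rab27b, which acts in granule release, and Itgb3, an integrin of platelets, stood at 54.0 ± 2.10, 53.4 ± 2.42 and 49.5 ± 1.25 (SD, n = 3). Vwf, the von Willebrand factor, had none. Myeloid genes had one in 16.7% ± 13.9 of 22 cases, with Cebpa, a factor of granulocyte formation, at 60.5 ± 2.81 (SD, n = 3). Cd68, a macrophage marker, and Spi1, the myeloid regulator PU.1, had a peak in replicates 2 and 3, and Timd4, a marker of resident macrophages, in none. Lymphoid genes had one in 23.3% ± 15.3 of 20 cases, with Ebf1, a B cell regulator, at 59.4 ± 1.25 and Tcf7, a T cell regulator, at 49.0 ± 2.76 (SD, n = 3). Lck, a T cell kinase, had one in replicates 2 and 3, and Zap70, another T cell kinase, in none.

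Among tissues that a liver should lack, neural genes had a promoter peak in 54.5% ± 19.8 of 22 cases, muscle genes in 26.7% ± 11.5 of 20 and germline genes in 21.7% ± 16.1 of 20 (SD, n = 3). The strongest were Mbp, a myelin protein, at percentile 74.3 ± 2.77, Actn3, a muscle actinin, at 91.7 ± 1.34, and Dazl, a germ cell RNA-binding protein, at 82.2 ± 4.43 (SD, n = 3). The window of Actn3 overlapped that of Zdhhc24. Among neural genes they were followed by Tubb3, a neuronal tubulin, at 54.7 ± 1.49, Grin1, a glutamate receptor subunit, at 53.9 ± 6.70 (SD, n = 3). In muscle, Mylpf, a myosin light chain whose window overlapped that of Tbc1d10b, stood at 81.4 ± 6.44 (SD, n = 3). Ryr1, a calcium channel, stood at 55.5 ± 0.203 (SD, n = 3). The oocyte factor Gdf9 and the meiotic protein Sycp3 had a peak in replicates 2 and 3, and Stmn2, Tnnt3 and Zp3 had none.

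The myeloid, lymphoid, mature hepatocyte, muscle and germline lists had promoter peaks less often than other genes in 3 of 3 libraries, with highest adjusted p-values of 0.00320, 0.0246, 0.00358, 0.0246 and 0.0246 (Fisher's exact test). None of these 5, nor any other list, was lower than lists matched on CpG content in all 3 libraries. The neural list was lower in rank, with a median percentile of 14.4 ± 24.9 (SD, n = 3) against 64.7 in matched lists (highest adjusted permutation p = 0.0195). This call ended with the most upstream TSS alone (15.03) and held, at 44.5, with windows of 2500 bp, at 21.6 with the false discovery rate and at 0 without replicate 2. The stem cell, megakaryocyte, endothelial and mesenchymal lists were called in none of the 3 comparisons, with highest adjusted p-values of 1, 0.861, 0.861 and 1 against other genes (Fisher's exact test). With windows of 2500 bp the calls against other genes ended for the myeloid (28.8%), lymphoid (31.7%), muscle (35.0%) and germline (31.7%) lists, and with the most upstream TSS alone for the muscle (26.7%) and germline (21.7%) lists. Without replicate 2 the mesenchymal, neural and germline lists were lower than matched lists, at mean percentiles of 0.223, 0.0475 and 0.030 among them, and the endothelial (22.2%) and mesenchymal (27.8%) lists were lower than other genes. The mean shares of the myeloid (9.09%), lymphoid (15%) and germline (12.5%) lists were then over 1.5 times lower. With equal numbers of the strongest peaks the mean share fell by over 1.5 times in 8 lists, the hepatoblast list among them. It was 11.1% for endothelial, 24.1% for mesenchymal, 12.1% for mature hepatocyte, 10.6% for myeloid, 11.7% for lymphoid, 31.8% for neural and 6.67% for germline genes. The endothelial and mesenchymal lists were then lower than other genes, and these with the neural and germline lists lower than matched lists. On the stricter list the mean fell by over 1.5 times in 6 lists: hepatoblast, endothelial (20.4%), mature hepatocyte (13.6%), lymphoid (13.3%), neural (34.8%) and germline (8.33%), and the neural and germline lists were lower than matched lists.

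Open regions away from promoters gathered near globin, erythroid, haem and iron, and housekeeping genes. Of the regions in all 3 libraries, 11005 lay more than 1000 bp from any TSS, and 48.6% of protein-coding genes had at least 1 within 50000 bp, with a mean of 1.00 per gene. The mean was 4.50 ± 1.958 (SD over 10 genes) for the globin genes and 2.62 ± 2.06 (SD over 34 genes) for the erythroid genes. It was 2.05 ± 1.54 (SD over 19 genes) for the haem and iron genes and 3.00 ± 2.27 (SD over 20 genes) for the housekeeping genes. At least 1 lay near 31 of the 34 erythroid genes and 17 of the 19 haem and iron genes. These 4 lists were higher than random lists, with adjusted permutation p-values of 0.001, 0.001, 0.0442 and 0.001, in a test on the pooled regions and not per library. The stem cell list, with 1.94 ± 2.36 (SD over 18 genes), did not pass at an adjusted permutation p of 0.0786. It was called within 20000 bp (1.28 against 0.421 in random lists, adjusted permutation p = 0.00525) and against random lists matched on gene density (1.94 against 0.844, 0.0112). The hepatoblast genes had 1.00 ± 1.52 (SD over 32 genes). The other 9 lists had means from 0.444 (mesenchymal) to 1.45 (myeloid) and were not called. The globin genes share their neighbourhoods and are not independent, and their call ended within 20000 bp (1.10 per gene). The haem and iron call ended against random lists matched on gene density (2.05 per gene) and without replicate 3 (2.21 per gene). Without replicate 1, the globin (14.1), erythroid (6.41), haem and iron (6.21) and housekeeping (4.80) lists were called against 2.34 per gene in random lists, and with regions in at least 2 libraries at 14.3, 6.53, 6.37 and 4.90. The erythroid and housekeeping calls held within 20000 bp (1.59 and 1.35 per gene), and all 4 held within 100000 bp (6.80, 4.21, 3.79 and 4.65).

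The strongest promoter regions, ordered by the worst of their signal ranks in the 3 libraries, included those of Dynlt1b, a dynein light chain (chromosome 17, 6430021 to 6430220), with signals of 18.0, 67.5 and 37.7 in replicates 1, 2 and 3. They also included those of Fzr1, an activator of the anaphase-promoting complex (chromosome 10, 81378481 to 81378820, signals of 13.0, 47.7 and 37.3), and Esrra, an orphan nuclear receptor (chromosome 19, 6921801 to 6922080, signals of 11.4, 41.9 and 35.7). Those of Sde2, Tbc1d14, Mplkip, Camsap1, Gpr155 and Hexim1 followed. The region with the best order of all lay 38 bp from the TSS of the non-coding gene Gm42418 (chromosome 17, 39846781 to 39846920), with signals of 62.8, 123.4 and 44.3. It lay inside CT010467.1, and its nearest protein-coding TSS was 103600 bp away. Away from promoters, the region first in this order lay in an exon of Lars2, a mitochondrial tRNA ligase, 16566 bp from the TSS of Limd1 (chromosome 9, 123461881 to 123462140, signals of 41.5, 70.1 and 31.1). It was followed by regions nearest to Gm43980, Gm25352, Trappc9, Gm15885, Cpeb4, Mir26b, Gm13448, Chd8 and Il31ra. The regions nearest to Limd1, Gm43980 and Gm25352 ranked 4, 7 and 8 in replicate 1 but 47, 88 and 221 in replicate 3. Whether sequence present in several copies gave the signal of these regions, or of that near Gm42418, was not tested. They are therefore not known to be open chromatin at these places. Of the 10 promoter regions 6, 7 and 5 stayed among the 10 without replicates 1, 2 and 3, and of the 10 distal regions 8, 8 and 7.

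Footprints, short stretches that a bound protein protects from cutting, were most enriched, by odds ratio, in the motifs of CTCF and NRF1. Of the motifs of red cell factors, KLF and the long NFE2 motif were enriched against control intervals in all 3 libraries, and GATA and its composite with TAL1 were not. Relative to their reversed strings, KLF and GATA differed little, as given below. By frequency the SP motif came first, in 10.7% of footprints, followed by the KLF (7.09%), GATA (2.56%), CTCF (1.83%) and NRF1 (1.16%) motifs. The motif of CTCF, which organises chromatin loops, had an odds ratio of 269 ± 71.6 (SD, n = 3) in footprints against control intervals beside them. It was followed by NRF1, a regulator of mitochondrial genes, at 30.2 ± 8.91 and RFX, a winged-helix family, at 11.2 ± 2.21 (SD, n = 3). The long NFE2 motif, bound by a red cell and megakaryocyte factor, stood at 9.45 ± 7.75 (SD, n = 3). The KLF motif, bound by KLF1 and its relatives, stood at 5.73 ± 0.691, the SP motif of GC boxes at 3.89 ± 0.579 and the ETS motif at 3.13 ± 0.635 (SD, n = 3). These 7 motifs were higher in 3 of 3 libraries (Fisher's exact test, adjusted over 21 motifs; for the long NFE2 motif the highest adjusted p was 8.9e-06). The motifs of the liver factors CEBP (0.624 ± 0.0707) and FOXA (0.413 ± 0.0409), and those of SOX (0.675 ± 0.0751), POU (0.688 ± 0.110) and the reversed GATA control (0.699 ± 0.0552), were lower in 3 of 3 libraries (SD, n = 3; highest adjusted p = 0.0457, Fisher's exact test). The reversed strings of CEBP (0.558 ± 0.0646), SOX (0.533 ± 0.0176) and POU (0.683 ± 0.167) were as low or lower, so these depletions were not specific to the motif, and that of FOXA was at 0.727 ± 0.0403 (SD, n = 3). Without extension of the footprints the ratios were 773 for CTCF, 95.003 for NRF1, 42.1 for the long NFE2 motif, 27.7 for RFX, 12.0 for KLF, 6.21 for SP and 0.162 for FOXA, and POU (0.454) was no longer called. CTCF was at 106 with control intervals 50 bp away, and the long NFE2 motif at 15.2 with those 200 bp away, where RFX was at 13.1, and at 5.04 without replicate 3.

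The GATA motif, bound by GATA1 in red cell precursors, had an odds ratio of 0.747 in replicate 1, 1.08 in replicate 2 and 1.44 in replicate 3, each past the test (highest adjusted p = 5.4e-07, Fisher's exact test), so it was not called. Its reversed string stood at 0.642, 0.703 and 0.752 in the same libraries. GATA was thus higher than its reversed string in each library, by 1.54 ± 0.373 times, against 1.49 ± 0.0486 times for KLF (SD, n = 3). The long NFE2 motif stood at 8.64 ± 0.789 times its reversed string and the composite with TAL1 at 4.01 ± 2.33 times (SD, n = 3). No test was run on these ratios. The composite of TAL1 and GATA, bound by the complex of both factors, had odds ratios of 1.07, 3.12 and 3.36, and the AP1 motif 0.834, 1.35 and 2.31. The NFY motif stood at 1.51 ± 0.437, RUNX at 1.15 ± 0.0837, PU1 at 0.817 ± 0.121, HNF4 at 1.83 ± 0.707, HNF1 at 2.72 ± 3.36 and MEF2 at 0.734 ± 0.0959 (SD, n = 3). Neither the composite, AP1 nor any of these 6 passed in all 3 libraries. Without replicate 1, GATA (1.26), the composite (3.24), AP1 (1.83), NFY (1.72) and RUNX (1.20) were called higher. The mean GATA odds ratio lay under 1 and was not called with control intervals 50 bp away (0.9503) and without replicate 3 (0.915). PU1 was called lower with control intervals 50 bp away (0.670) and was at 0.492, not called, without extension, where HNF4 was at 1.16. HNF1 was at 0.794 without replicate 2, not called. With control intervals 200 bp away, GATA (1.52), the composite (4.66) and NFY (2.22) were called higher and the reversed control (0.814) and POU (0.707) were no longer lower. The reversed strings of the SP (3.33 ± 0.553), KLF (3.86 ± 0.436) and NRF1 (9.23 ± 1.70) motifs (SD, n = 3) were also over 1. The motifs stood at 1.17 ± 0.0256, 1.49 ± 0.0486 and 3.28 ± 0.903 times their reversed strings (SD, n = 3). Base composition is thus not excluded as a part of these enrichments. The reversed SP and KLF strings resemble their motifs, so the control cannot fully tell composition from sites there. Footprints held 65.6%, 61.6% and 60.4% G and C against 61.2%, 56.2% and 55.5% in the control intervals.

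Replicates 1, 2 and 3 held 89836, 342756 and 156638 footprints, a mean of 196410 ± 131067 (SD, n = 3), with a median width of 10 bp in each. Without replicate 2 the mean was 123237. Of the footprints, 84.5% ± 6.57 lay in a peak, and 77.9% ± 4.31 of the peaks held a footprint (SD, n = 3). In replicate 1, 73.2% of the footprints overlapped a footprint of replicate 2 by at least 1 bp and 59.9% one of replicate 3. Of those of replicate 2, 17.2% overlapped one of replicate 1 and 27.5% one of replicate 3, and of those of replicate 3, 32.3% one of replicate 1 and 63.7% one of replicate 2. With at least 50% reciprocal overlap these shares lay between 10.25% and 42.0%.

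**Figure D4:**
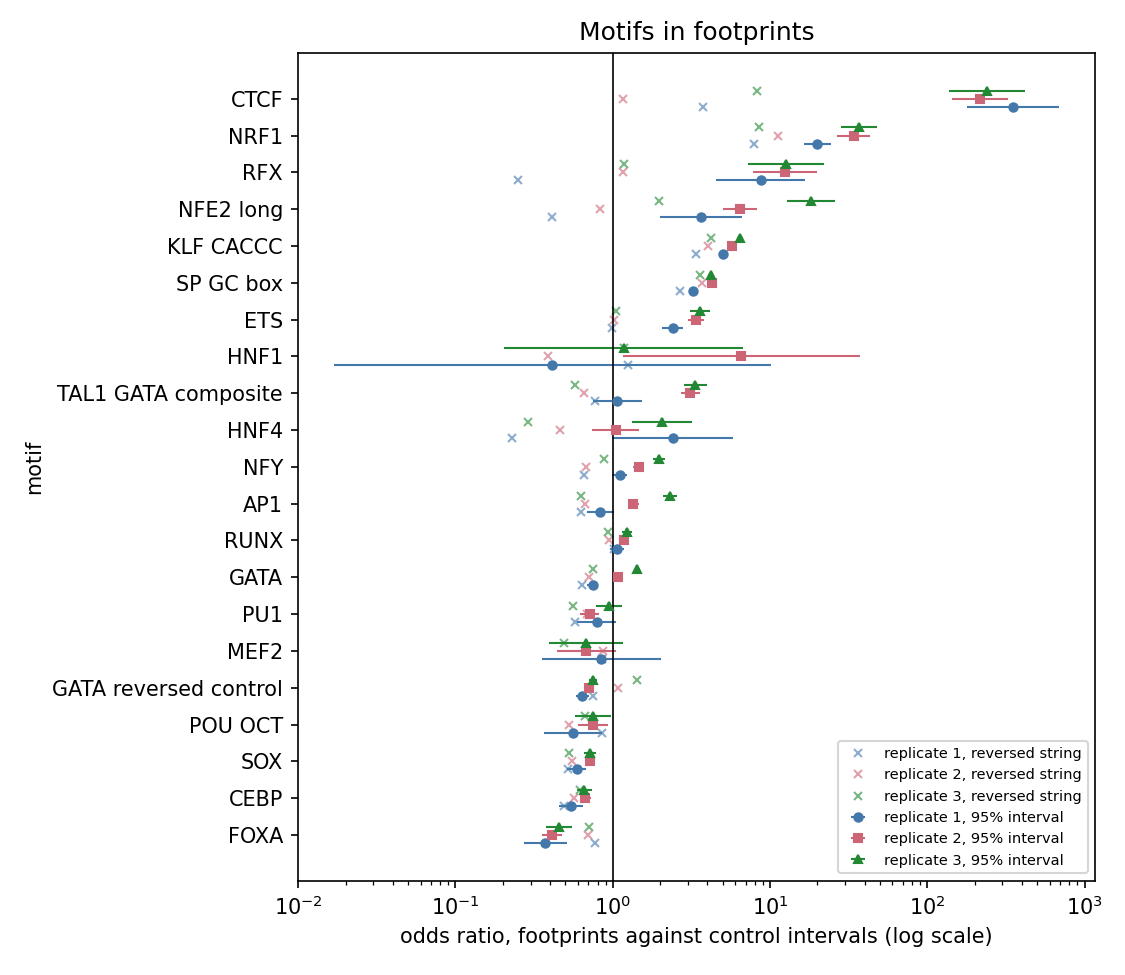
Odds ratio (log scale) of each motif in footprints against control intervals 100 bp away in replicates 1, 2 and 3, with 95% intervals; crosses show the reversed string of each motif. CTCF lies farthest to the right (mean 269) and FOXA farthest to the left (mean 0.413), and GATA lies at 0.747, 1.08 and 1.44 in replicates 1, 2 and 3.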

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

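The most upstream TSS alone, random lists matched on gene density, lists without copied promoters and the changes to the strongest regions were chosen after the data were seen. Of 232 values of the main results under alternatives, 202 kept their call over the libraries or, where no call is made, moved by less than the spread between replicates or by at most 1.5 times. This count includes lists not called in either setting, such as the hepatoblast share, which went from 54.2% to 25.0%. It also includes values with a wide spread, such as the overlap of peaks, at 60.1% and between 48.2% and 72.4% under alternatives. The count is thus not a measure of how stable the values were. No call over all libraries turned to the opposite direction, but within replicate 2 the hepatoblast list went from higher to lower than random lists with equal numbers of the strongest peaks (18.75%), and the mean GATA odds ratio, not called in either setting, crossed 1 with control intervals 50 bp away (0.9503) and without replicate 3 (0.915). The cause of the changes that follow was not tested, except that leaving out a library asks for calls in fewer libraries. With equal numbers of the strongest peaks the Jaccard index was 0.455, the hepatoblast share was 25.0%, and 4 lists were lower than random lists, against 0 in the main setting. The stricter peak list gave 2 lists lower than random lists, and 10 regions at the alpha-globin and 3 at the beta-globin locus. With windows of 2500 bp the haem and iron call against other genes ended (94.7%), 1 list was lower than other genes in place of 5, and the globin list was called in rank (48.1). With the most upstream TSS alone the haem and iron share (80.7%) and the erythroid rank (69.5) were no longer called, 3 lists were lower than other genes and 0 were lower in rank. Against unmatched random lists the globin list was not called (percentile 52.0), the haem and iron list was (99.86), and 5 lists were lower. With the false discovery rate in place of the signal the erythroid (63.8) and haem and iron (81.3) ranks were not called, which left 0 lists higher in rank in place of 3. Within 20000 bp the globin genes had 1.10 distal regions each and were not called, and against lists matched on gene density the haem and iron genes (2.05) were not called. Control intervals 200 bp away left 3 motifs depleted in place of 5. With 1 replicate left out the Jaccard index lay between 0.209 and 0.350, lists lower than random lists between 0 and 3, the hepatoblast percentile among random lists between 49.998 and 99.995, the globin rank between 27.9 and 56.99, haem and iron distal regions between 2.05 and 6.21, enriched motifs between 7 and 12, footprints per library between 123237 and 249697, and regions in every library used between 16 and 38 at the alpha-globin and between 7 and 17 at the beta-globin locus. Of 504 values of named genes 57 moved by more than the spread between replicates, and of 504 other values 30 became called, 13 were no longer called and 1 moved. A stricter threshold on footprints and equal numbers of the strongest footprints could not be run, since the footprints carry a constant in place of a score. Read totals were not used, so how far depth limits the regions found is not known; the globin region counts and the number of enriched motifs were higher without replicate 1, which had the fewest peaks.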

Other observations

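The copied-promoter test against genes of equal CpG content and the test of GATA sites away from promoters were set before their results were seen. So was an earlier form of the test of GATA sites in regions called in all 3 libraries, whose bounds were changed after. All the other tests below were chosen after. The promoters of E2f2, a cell cycle regulator, Rhag, a Rhesus-associated channel, Gfi1b, a repressor of red cell and platelet formation, and Pklr made up the 4 erythroid genes without a peak in replicate 1, and all 4 had one in replicates 2 and 3. Their signals were 2.56, 1.71, 2.35 and 2.49 in replicate 2 and 2.80, 3.41, 2.56 and 2.05 in replicate 3. At the beta-globin locus, a region 3739 bp from the TSS of the olfactory receptor gene Olfr65 (chromosome 7, 103910081 to 103910320) had signals of 0.649, 3.66 and 7.25 in replicates 1, 2 and 3.

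Hepatoblast promoters had a peak in 12.5% of cases in replicate 1 against 81.3% and 68.8% in replicates 2 and 3, and with equal numbers of the strongest peaks in 12.5%, 18.75% and 43.75%. For the difference from replicate 2, lower depth or weaker signal at these promoters stays open: with equal numbers the list had 4 genes with a peak in replicate 1 and 6 in replicate 2, too few differing genes to test, while it lay at percentile 0.03 of random lists matched on signal in replicate 2 (mean 36.0%). For the difference from replicate 3 the values of these 2 libraries argue against it: with equal numbers 11 genes had a peak in replicate 3 and not in replicate 1, and 1 the reverse (p = 0.00635, exact McNemar test). The p-values in this paragraph are unadjusted, and the list was chosen after its spread was seen. The tests compare 1 library with another over genes, which are not replicates, so they describe these libraries alone. The list lay at percentile 0 of lists matched on signal in replicate 3 (51.3%), as did the erythroid list, with the globin list at 0.205 and the myeloid list at 0.69, so a low share at matched signal was not particular to it. Matched on that signal and CpG together (43.9%) it lay at percentile 0, against weaker signal with low CpG content, and the erythroid list at 2.59. Matched on CpG alone (37.8%) it lay at percentile 0 in replicate 1 but at 91.3 in replicate 3 with equal numbers, against fewer peaks at CpG-poor promoters for that difference. Fewer cells that are not blood cells in the sample of replicate 1 would lower the endothelial and mesenchymal lists too, and this stays open. Of these 36 genes 8 had a peak in replicate 1 and 10 in replicate 3, a change not told apart from that of the hepatoblast genes (p = 0.0543, Fisher's exact test on the genes that differed), whereas with equal numbers it was 8 and 5 and differed from theirs (p = 0.00879). Also open, untested, are a loss of hepatoblasts alone, a difference in how the tissue of replicate 1 was prepared, or a sample of another origin, and no biological explanation was tested, since the design has a single group.

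Of 5456 CpG-rich promoters, 137 had no listed peak in any library. A candidate explanation is promoter sequence copied elsewhere in the genome, so that reads placed in several spots were removed: of 1046 copied promoters 9.27% had a peak in any library against 25.2% in lists matched on CpG, a difference of -15.9 percentage points, below all 1000 random lists. Matching on CpG cannot tell removed reads from genes that are not in use, and Hba-a1 and Hba-a2, also copied, had peaks in replicates 2 and 3. Copying fits Slc25a37, whose window is copied over its whole length, but of the 137 promoters 9 were copied, or 6.57% against 0.320% of CpG-rich promoters with a peak, which argues against copying as the explanation for most of them. What removed the peaks of the rest, or whether these promoters were closed, stays open, and no biological explanation was tested.

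The GATA motif had an odds ratio under 1 in replicate 1 (0.747) and over 1 in replicates 2 and 3. A larger share of promoter footprints in replicate 1 would put its odds ratio over 1 among footprints more than 1000 bp from any TSS, where it was 0.733 (95% interval 0.662 to 0.813) against 1.23 and 1.61 in replicates 2 and 3. This argues against it as the whole cause, although within 1000 bp of a TSS the ratios were under 1 in replicates 1 (0.601) and 2 (0.743) and at 0.929 (0.859 to 1.005) in replicate 3. Whether the ratios over 1 in replicates 2 and 3 come from regions called in fewer than 3 libraries stays open: in regions called in all 3 they were 1.03 (0.977 to 1.09) and 0.9901 (0.931 to 1.053), but 1.38 (1.29 to 1.48) and 1.60 (1.46 to 1.75) against control intervals 200 bp away. An earlier form of this test, set before its result was seen, asked replicate 3 to stay over 1 and met neither of its bounds. Against control intervals 200 bp away replicate 1 had 1.19 (1.01 to 1.40) more than 1000 bp from any TSS, so GATA sites in the control intervals beside footprints are a candidate source of its ratio under 1 there. Within 1000 bp of a TSS it stayed under 1 at 0.678 (0.596 to 0.770), as did replicate 2 at 0.651 (0.611 to 0.693), which argues against that source at promoters. Why more GATA sites lay beside than in the footprints of replicate 1 stays open, lower depth, different regions called and base composition included, and no biological explanation was tested. Against control intervals 100 bp away the reversed string, the control for base composition, was also under 1 in every library, at a mean of 0.699 ± 0.0552 (SD, n = 3). In replicate 1 it lay below the GATA motif, so the ratio under 1 there was not specific to that motif.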
